A study of Mus musculus with 2 samples.

How the data were processed

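RNA was measured in J-RGCs, a type of retinal ganglion cell, isolated from mouse retina at postnatal day 6. Per the labels' protocols and the series design, the cells carried green fluorescent protein from a transgenic line specific to the type and were enriched with magnetic beads and flow cytometry. RNA was extracted with PicoPure columns, and cDNA libraries were made with the Nugen Ovation Ultralow V2 kit. There were 2 libraries in 1 group, named A and B in the labels, each a pool of 5 to 6 animals from a different litter. The series holds no second cell type, age or treatment, so every comparison is between genes within these cells or between the 2 libraries.

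The authors deposited whole-number read counts per gene symbol, 1 file per library. The submitters' processing notes name Trimmomatic 0.32, TopHat2 2.0.10, HTSeq 0.6.1 and the mm9 build. The settings, the gene annotation and whether strand was used in counting are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The files give symbols without coordinates, and the GENCODE M21 reference at hand is on another build, so no coordinates are reported. It was used only for summed exon lengths. The deposited counts covered 24015 gene symbols in each file, of which 7046 had no read in either library. Library A held 7916204 gene counts and library B 13744313. The summary lines at the end of each file were kept out of all totals. Of the reads in the files, 26.8% in A and 30.9% in B were assigned to a gene, 54.3% and 47.9% fell outside annotated features, 18.5% and 20.8% aligned to several places, and 0.313% and 0.357% were ambiguous between genes. Neither file listed any unaligned read, so these are shares of what was aligned and reads that did not align may be missing. Whether a read aligned to several places was counted once or once per place is not given in the sources used here. All of these shares are uncertain for that reason. No mitochondrially encoded gene was listed. Genes with near-identical copies lose reads under such counting, so the globin genes, ribosomal protein genes and other multicopy families are uncertain here. The ribosomal transcript Rn45s, Lars2 and Gm20594, which can collect ribosomal RNA reads, held 3.10% of gene counts in A and 3.88% in B.

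Counts were divided by the library's gene total and scaled to a total of 1000000 (CPM), and log2 values were taken with a pseudocount of 0.5. A gene was called detected at a CPM of at least 1 in both libraries. Values are given as mean ± SD over n = 2 libraries unless 2 values are given, A before B. CPM is not corrected for transcript length, so a longer transcript has a higher CPM at the same number of molecules. At the floor of 3 counts, a gene with no read has an upper limit of 0.379 CPM in A and 0.218 CPM in B. Amplified reads carry no molecular identifiers, so this limit covers counting error only.

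With 1 group there was no contrast for edgeR's quasi-likelihood test. The spread between the libraries was estimated with edgeR 4.0.16 in R 4.3.3 as a biological coefficient of variation from an intercept-only fit with TMM factors, over the 11272 genes kept by its expression filter. Each gene's counts in the 2 libraries were compared by an exact two-sided binomial test, doubling the smaller tail, with Benjamini-Hochberg adjustment over genes with at least 10 counts in all. A gene was called beyond counting noise at an adjusted value under 0.05 and a change of at least 2-fold. That test compares these 2 libraries and says nothing of conditions. Separately amplified libraries differ by more than the counting error of their reads, so many such genes were expected and their number tests nothing. The ratio of 2 genes was given a 95% interval from counting error and edgeR's trended dispersion. With 1 library left out the dispersion was kept and the interval is wider by construction. A call that ends then need not mean that the ratio moved. Gene lists were compared by their median log2 level. The percentile of a list's level was taken among 10000 random lists of its size, drawn from genes with a count. The percentile of its B over A ratio was taken among 10000 random lists matched on level in 20 bins, and a list was called apart below the 2.5 or above the 97.5 percentile. Genes are not independent replicates, so these percentiles describe the libraries. Another list was counted as below the ganglion cell list when it was lower in both libraries by more than 2 SD of the difference. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the rest.

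The statistics were tested on simulated data built from the real gene means and totals. For replicate agreement, simulated coefficients of variation of 0.3, 0.6 and 0.9 were estimated at 0.296, 0.565 and 0.777 over 12452, 11796 and 10754 genes, so large values were underestimated. For the binomial test over 13944 genes with 3-fold changes, 96.0% of 200 changed genes were recovered with 2 unchanged genes called. For 8-fold changes over 13976 genes it recovered 100% with 14 unchanged genes called. The interval for a ratio held the true value in 93.9% of simulated gene pairs, drawn from 5885 genes. Those pairs were random and the interval was given their true dispersion. The family pairs were picked by rank with an estimated dispersion, so their coverage was not tested. Of simulated lists of 12 genes, 7.0% with no shift and 93.5% with a log2 shift of 1 were called apart, over 16969 genes.

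The gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The lists covered the ganglion cell class, 12 other cell types or states, J-RGCs and 4 other ganglion cell types, 42 transcription factors of ganglion cell subclasses, 18 families of recognition, guidance, receptor and channel genes and secreted peptides, and handling and sex-linked genes. The rule named the 25 highest genes without ribosomal, mitochondrial or unnamed predicted genes, all members of the ganglion cell and ganglion cell type lists, the 15 highest subclass factors, the 4 highest members of each other cell type and handling list, the 3 highest members of each family with any J-RGC gene in it, and the 10 genes farthest apart in each direction between the libraries among those beyond counting noise with a mean CPM of at least 10. Some genes that meet the rule are not reported here. Other genes named, the 16-fold limit, and ratios of genes that are not neighbours in rank, except those between members of the J-RGC list, were chosen after their values were seen. Of the symbols on the lists, 9 were not in the files, 8 of them because the files use the gene's other symbol, also listed. Alternatives were TMM and DESeq2 1.42.0 scaling, other pseudocounts, thresholds and filters, length correction, thinning of the deeper library, lists without their highest member, and leaving out each library. The dispersion was also estimated with DESeq2. Some of the alternatives and 11 further lists were added after seeing the data and are named where used. The sequence of the fluorescent protein was not analysed here.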

Results

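The data describe the genes used by J-RGCs, ganglion cells of the mouse retina marked by the adhesion molecule Jam2 (JAM-B), at postnatal day 6. Library A held 7916204 gene counts and library B 13744313, from separate litters. At a CPM of at least 1 in both libraries, 11241 genes were detected, with 11700 in A alone and 13130 in B alone.

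Among the most abundant named transcripts Map1b, a microtubule-associated protein, stood at 15367 ± 2126 CPM, and Snap25, of the synaptic vesicle fusion machinery, at 11944 ± 1405 CPM. The noncoding RNAs Malat1 and Meg3 followed at 9704 ± 2778 and 5177 ± 2411 CPM. The light neurofilament gene Nefl reached 4815 ± 1800 CPM, the Golgi trafficking gene Rab6b 4809 ± 394 CPM, and the tubulins Tubb4a and Tuba1a 4522 ± 845 and 4388 ± 559 CPM. The axonal adhesion molecule L1cam stood at 2943 ± 819 CPM. Jam2, the gene that defines the type, ranked 48 among all genes at 1774 ± 807 CPM. The 25 highest genes took 15.7% ± 0.761 of gene counts. Of the 25 highest named genes, 20 lay within 2-fold between the libraries. Tmem245 (16137 and 49.1 CPM), Smc5 (6060 and 123 CPM), Rev3l (8488 and 1467 CPM) and Ndrg4 (6805 and 957 CPM) were far higher in library A, and Eef1a1 stood at 3380 and 1681 CPM. Lars2, at 11468 ± 340 CPM, can collect ribosomal RNA reads and is uncertain.

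Genes shared by ganglion cells as a class were all present. All 20 members of that list were detected, 19 of them above 100 CPM in both libraries, and the list's median of 512 ± 179 CPM lay above every one of 10000 random lists in each library. Slc17a6, the vesicular glutamate transporter of ganglion cells, stood at 1585 ± 207 CPM, the RNA-binding protein gene Rbpms at 1287 ± 377 CPM, and Nefm and Stmn2 at 2521 ± 904 and 1898 ± 352 CPM. Of the POU-domain factors of ganglion cells, Pou4f2 (749 ± 371 CPM) and Pou4f1 (555 ± 197 CPM) were not separated from each other, with a ratio of 1.35 and a 95% interval of 0.498 to 3.65. Pou4f3 was far lower at 5.41 ± 2.12 CPM, and Pou4f2 exceeded it 138-fold, with an interval of 45.9 to 417. Thy1 stood at 506 ± 245, Gap43 at 427 ± 182, Elavl4 at 367 ± 17.2, Tubb3 at 264 ± 97.3, Rbpms2 at 243 ± 49.5, Sncg at 179 ± 54.8, Isl1 at 147 ± 59.0 and Nrn1 at 136 ± 13.5 CPM. Between the libraries 18 of the 20 genes lay within 2-fold.

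**Figure D1:**
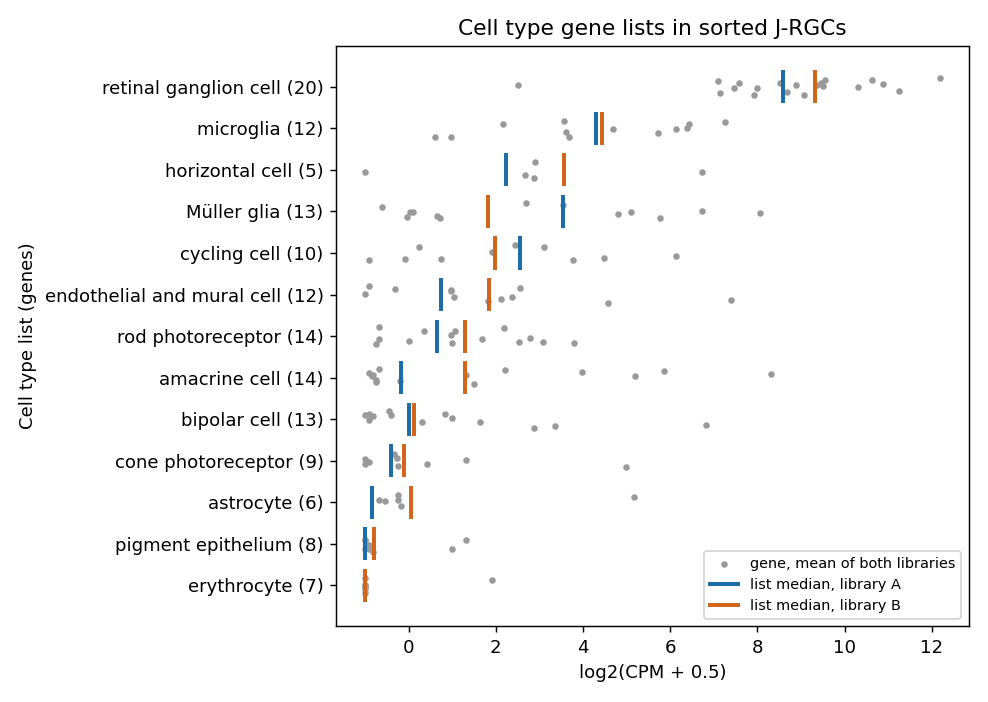
Levels of the genes on the ganglion cell list and on 12 lists of other cell types or states, as log2(CPM + 0.5) on the horizontal axis. Grey points are genes, averaged over both libraries, and the bars are the list medians in libraries A and B. The ganglion cell medians of 8.59 and 9.32 lie above those of every other list, and the microglia list comes next at 4.31 and 4.43.

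Whether the sort held other retinal cells was asked with lists of their genes. All 12 other lists lay below the ganglion cell list in both libraries by more than 2 SD of the difference. How high each list stands in its own cells at postnatal day 6 was not measured. A low median can thus come from genes that are weak at that age or from the choice of genes. The differences do not give shares of cells or exclude other cells. The difference on the log2 scale was 7.98 ± 0.0580 for rods, 9.20 ± 0.292 for cones, 8.89 ± 0.439 for bipolar cells, 8.39 ± 0.526 for amacrine cells, 6.06 ± 0.436 for horizontal cells, 9.34 ± 0.118 for astrocytes, 7.66 ± 0.265 for endothelial and mural cells, and 9.85 ± 0.376 for pigment epithelium. These sizes depend on members near 0: with members of at least 10 counts only, they were 5.86 for amacrine cells, 7.43 for bipolar cells, 8.08 for cones and 7.80 for pigment epithelium. Over all settings they ranged from 6.84 to 8.31 for rods, 8.08 to 10.15 for cones, 7.43 to 9.59 for bipolar cells, 5.86 to 9.06 for amacrine cells, 8.24 to 10.64 for astrocytes, 6.998 to 7.95 for endothelial and mural cells and 7.80 to 11.88 for pigment epithelium. Rod genes included Pde6b (8.53 ± 4.55 CPM), Nr2e3 (9.85 and 4.15 CPM) and Rom1 (6.06 ± 4.29 CPM). Of the cone genes Cngb3 stood at 35.6 ± 23.8 CPM, Gngt2 at 2.07 ± 0.780 CPM, Pde6c at 0.953 ± 0.812 CPM and Gnat2 at 0 and 0.873 CPM. Of the 8 pigment cell genes 1 was detected and 3 had no count in either library, with Tyr at 2.07 ± 0.780 and Best1 at 1.61 ± 1.02 CPM.

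Microglia genes stood higher than those of the other lists. Of the 12 genes on that list 10 were detected and 7 exceeded 10 CPM in both libraries, and the median was 19.8 CPM in A and 21.5 CPM in B, which was 4.58 ± 0.425 below the ganglion cell list on the log2 scale and 3.61 below with length correction. The purinergic receptor gene P2ry12 stood at 85.3 ± 0.0869 CPM, the colony-stimulating factor receptor gene Csf1r at 83.6 ± 5.00 CPM and the protease gene Ctss at 71.8 ± 22.4 CPM. The list's level was at the 90.8 and 87.1 percentile of random lists in A and B. Single members of other lists also stood well above their list's median. Gad2, a GABA-synthesising enzyme, reached 57.6 ± 1.14 CPM, and the factors Tfap2b and Tfap2a 36.6 ± 7.97 and 16.6 ± 9.34 CPM, while Chat, Th, Slc18a3 and Slc32a1 of the same amacrine list lay below 1 CPM in both libraries. Slc17a6 exceeded Gad2 27.5-fold, with a 95% interval of 10.7 to 71.1. Prkca stood at 113 ± 24.8 CPM among bipolar genes, beside Grm6 (96.4 and 0.582 CPM), Car8 (23.9 and 1.75 CPM) and Trpm1 (2.63 ± 0.216 CPM). Onecut2 reached 106 ± 19.6 CPM among horizontal cell genes, and Onecut1, Calb1 and Prox1 stood at 7.82 ± 7.67, 7.76 ± 5.08 and 6.93 ± 1.46 CPM. Some of these genes are also found in other retinal neurons, and which cells gave their reads was not tested.

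The Müller glia list, 5.05 below the ganglion cell list in A and 7.49 in B, included Dkk3 at 270 ± 66.4 CPM, Glul (glutamine synthetase) at 108 ± 29.4 CPM, Vim at 57.3 ± 26.3 CPM and Clu at 35.9 ± 18.3 CPM, whereas Rlbp1 stood at 0 and 1.60 CPM. Of the astrocyte list Aldoc reached 36.7 ± 12.1 CPM, and Gfap stood at 0 and 1.09 CPM, S100b at 0.415 ± 0.484 CPM and Aldh1l1 at 0.391 ± 0.374 CPM. The mural cell genes Rgs5 (342 and 82.4 CPM), Pdgfrb (51.9 and 10.3 CPM) and Kcnj8 (9.98 and 2.76 CPM) were higher in A, while the endothelial receptor gene Tek was higher in B (1.64 and 8.22 CPM). The cycling cell list was 6.04 below the ganglion cell list in A and 7.34 in B, with the proliferation gene Mki67 at 116 and 41.8 CPM, Top2a at 22.4 ± 7.80, Ccna2 at 13.2 ± 1.94 and Ccnb1 at 8.49 ± 3.36 CPM. In the erythrocyte list Alas2 stood at 3.29 ± 0.902 CPM and the 6 globin genes were listed at 0, which is uncertain because globin copies share reads, so its difference of 9.95 ± 0.515, or 7.05 with members of at least 10 counts only, is not a measure of blood.

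Without another cell type, the data show whether genes tied to J-RGCs were read, not whether they mark the type. All 4 genes on the J-RGC list were detected above 10 CPM in both libraries. Jam2 far exceeded the others, 23.3-fold over the T-box factor gene Tbr1 (76.0 ± 21.4 CPM; 95% interval 9.02 to 60.4), 27.0-fold over the sortilin-type receptor gene Sorcs3 (65.8 ± 16.4 CPM; interval 10.4 to 69.7) and 41.4-fold over the cadherin gene Cdh8 (42.9 ± 19.3 CPM; interval 15.7 to 109). In library A alone these folds were 38.5, 43.3 and 80.3, and in B alone 13.2, 15.6 and 21.3, with intervals that excluded 1. The study may have chosen Sorcs3 and Cdh8 on these libraries, so their presence is not independent evidence. The list's median was 70.9 ± 18.9 CPM, at the 95.9 and 97.6 percentile of random lists in A and B.

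Genes tied to other ganglion cell types were present too. The J-RGC list exceeded 3 of the 4 other type lists in both libraries. Jam2 defines the sorted type, and Sorcs3 and Cdh8 may have been chosen on these libraries, so this count is not independent evidence. On the log2 scale the J-RGC list lay above the ON-OFF direction-selective list by 0.773 ± 0.0852, the alpha list by 2.37 in A and 3.47 in B, and the intrinsically photosensitive list by 0.60 in A and 1.35 in B. The last of these did not exceed 2 SD. It lay below the F-RGC list, with a difference of -2.12 in A and -0.64 in B. Over all settings these differences ranged from 0.64 to 1.64 for the direction-selective list, 1.36 to 4.92 for the alpha list, 0.60 to 1.83 for the photosensitive list and -2.12 to -0.42 for the F-RGC list. That list holds Foxp2, at 668 and 156 CPM, and Foxp1, at 102 ± 12.1 CPM. Tbr1 was 0.184-fold of Foxp2 (95% interval 0.0743 to 0.458), but 0.0911-fold in A alone and 0.584-fold in B alone, where the interval of 0.162 to 2.11 held 1. Among direction-selective genes the chromatin organiser Satb1 stood at 364 ± 58.3 CPM, Fstl4 at 93.8 ± 30.5, Cdh6 at 44.4 ± 20.4, Cartpt, a neuropeptide gene, at 26.3 ± 20.1, Mmp17 at 23.5 ± 19.7 and Col25a1 at 10.7 ± 4.66 CPM. Among genes of photosensitive cells Tbx20 stood at 82.2 ± 18.8, Eomes (Tbr2) at 39.9 ± 11.3, Adcyap1 at 31.6 ± 2.48 and melanopsin (Opn4) at 20.5 ± 7.69 CPM. Tbr1 exceeded Opn4 3.71-fold (95% interval 1.48 to 9.30), although in B alone the interval held 1 (3.52-fold, 0.967 to 12.8). It was not separated from Eomes (1.91-fold, 0.811 to 4.48) or Tbx20 (0.924-fold, 0.400 to 2.13; log2 ratio 1.11 with length correction). Against Cartpt it was 1.502-fold in A (0.434 to 5.20) and 7.55-fold in B (2.18 to 26.2). Of the alpha genes Nefh stood at 67.6 ± 47.8 and Spp1 at 8.93 ± 2.55 CPM. Kcng4, a potassium channel subunit of alpha cells, had 0 counts in both libraries, which allows up to 0.379 and 0.218 CPM. These lists hold between 2 and 6 genes, and levels of different genes do not give shares of cells.

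**Figure D2:**
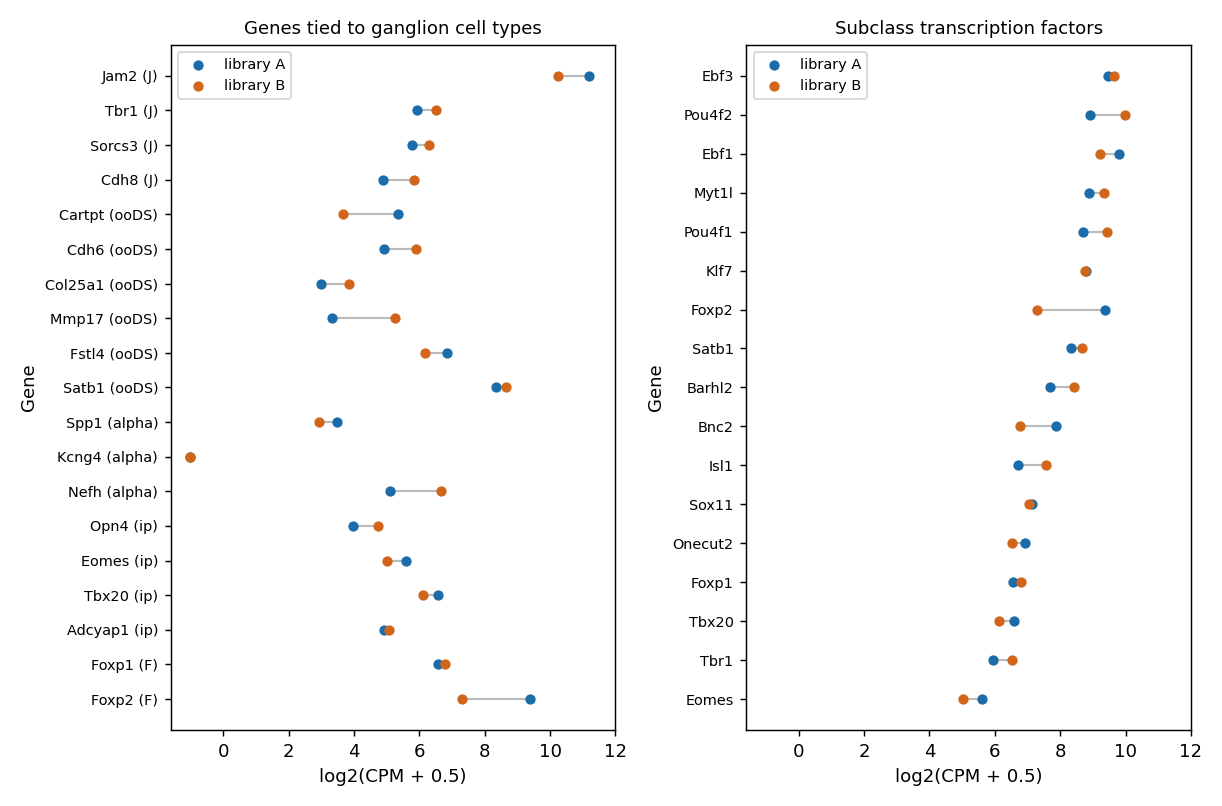
Levels of genes tied to ganglion cell types (left) and of subclass transcription factors, 14 of the 15 highest with Tbx20, Tbr1 and Eomes (right), as log2(CPM + 0.5) on the horizontal axes, with 1 point per library and a grey line joining the 2. In the left panel J, ooDS, alpha, ip and F mark the J-RGC, ON-OFF direction-selective, alpha, intrinsically photosensitive and F-RGC lists. Jam2 stands highest at 2344 and 1203 CPM, and Kcng4 had no counts.

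Of the 42 transcription factors tied to ganglion cell subclasses 39 were detected, 13 of them above 100 CPM in both libraries. Ebf3 (755 ± 66.3 CPM), Pou4f2 and Ebf1 (742 ± 204 CPM) were highest. Ebf3 over Pou4f2 was 1.01-fold, with a 95% interval of 0.369 to 2.76, and the order of these genes differed between the libraries. Myt1l (563 ± 128 CPM), Pou4f1 and Klf7 (440 ± 5.60 CPM) came next. Among the 15 highest were also Foxp2, Satb1, Barhl2 (275 ± 99.9 CPM), Bnc2 (172 ± 90.0 CPM), Isl1, Sox11 (136 ± 5.81 CPM), Onecut2 and Foxp1. Tbr1 ranked 18. It was lower than Satb1, at 0.209-fold with an interval of 0.0848 to 0.514. With length correction the log2 ratios of Tbr1 to Satb1 and to Foxp2 were -0.77 (-2.07 to 0.53) and -1.19 (-2.51 to 0.12), which ended both calls. Tbr1 was higher than Neurod2, 7.55-fold with an interval of 2.76 to 20.7. Dlx1 stood at 0 and 0.0728 CPM and Dlx2 at 0 and 0 CPM, at or under the floor.

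Among recognition molecules the leading member was the same gene in both libraries in most families but was seldom separated from the next. Over all 18 families of recognition, guidance, receptor, channel and secreted genes, 14 had the same leading gene in A and B, and in 3 the 95% interval of its ratio to the next excluded 1. Jam2 led its own family, 6.78-fold over Cxadr (262 ± 52.6 CPM; interval 2.504 to 18.3), with Jam3 at 8.55 ± 1.19 CPM. Contactin 1 (Cntn1), an axonal adhesion molecule, stood at 1806 ± 591 CPM, 4.66-fold over Dscam (388 ± 105 CPM; interval 1.70 to 12.8), with Cntn4 at 80.4 ± 44.4 CPM. The receptor gene Epha5 stood at 290 ± 72.7 CPM, 2.86-fold over Epha4 (101 ± 25.2 CPM; interval 1.16 to 7.02), with Epha7 at 57.7 ± 9.16 CPM. Jam2 over Cxadr was 10.4-fold in A alone. Without library A its log2 ratio was 2.01 with an interval of -0.02 to 4.04, and the Epha5 call ended without either library (1.52 and 1.51) and with length correction (0.84). The Epha5 log2 ratio was 1.51 with both libraries, so leaving 1 out widened its interval and hardly moved the ratio. The classical cadherins were led by Cdh2 (343 ± 22.3 CPM), Cdh4 (296 ± 74.6 CPM) and Cdh11 (166 ± 10.8 CPM). Cdh8 ranked 9 of 19, and Cdh2 exceeded it 8.01-fold (interval 3.20 to 20.04). Among sortilins Sorcs1 (288 ± 62.0 CPM) exceeded Sorcs3 4.37-fold (interval 1.79 to 10.7), though in B alone the interval held 1 (3.15-fold, 0.893 to 11.1), with Sort1 at 176 ± 29.1 and Sorl1 at 111 ± 14.6 CPM.

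All 10 delta-protocadherins were above 10 CPM in both libraries, 8 of them above 100, with Pcdh10 at 817 ± 295, Pcdh7 at 688 ± 19.2 and Pcdh11x at 385 ± 10.6 CPM. All 14 teneurin, latrophilin, FLRT and LRRTM genes were detected, led by Tenm3 (838 ± 214 CPM), Flrt2 (1217 and 296 CPM) and Tenm2 (565 ± 15.3 CPM). Of the semaphorins Sema6a stood at 1224 ± 164 CPM, whereas Sema5a (2693 and 265 CPM) and Sema3e (1088 and 182 CPM) were far higher in A. Their receptors included Plxna1 at 304 ± 1.45, Plxna2 at 200 ± 35.4 and Nrp1 at 179 ± 65.8 CPM. The ephrins were lower, with Efna5 at 89.9 ± 25.1, Efnb2 at 58.6 ± 19.8 and Efna2 at 3.41 and 87.7 CPM. Of the Slit and netrin receptors Robo2 stood at 944 ± 160, Neo1 at 450 ± 91.4 and Unc5c at 452 and 180 CPM.

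**Figure D3:**
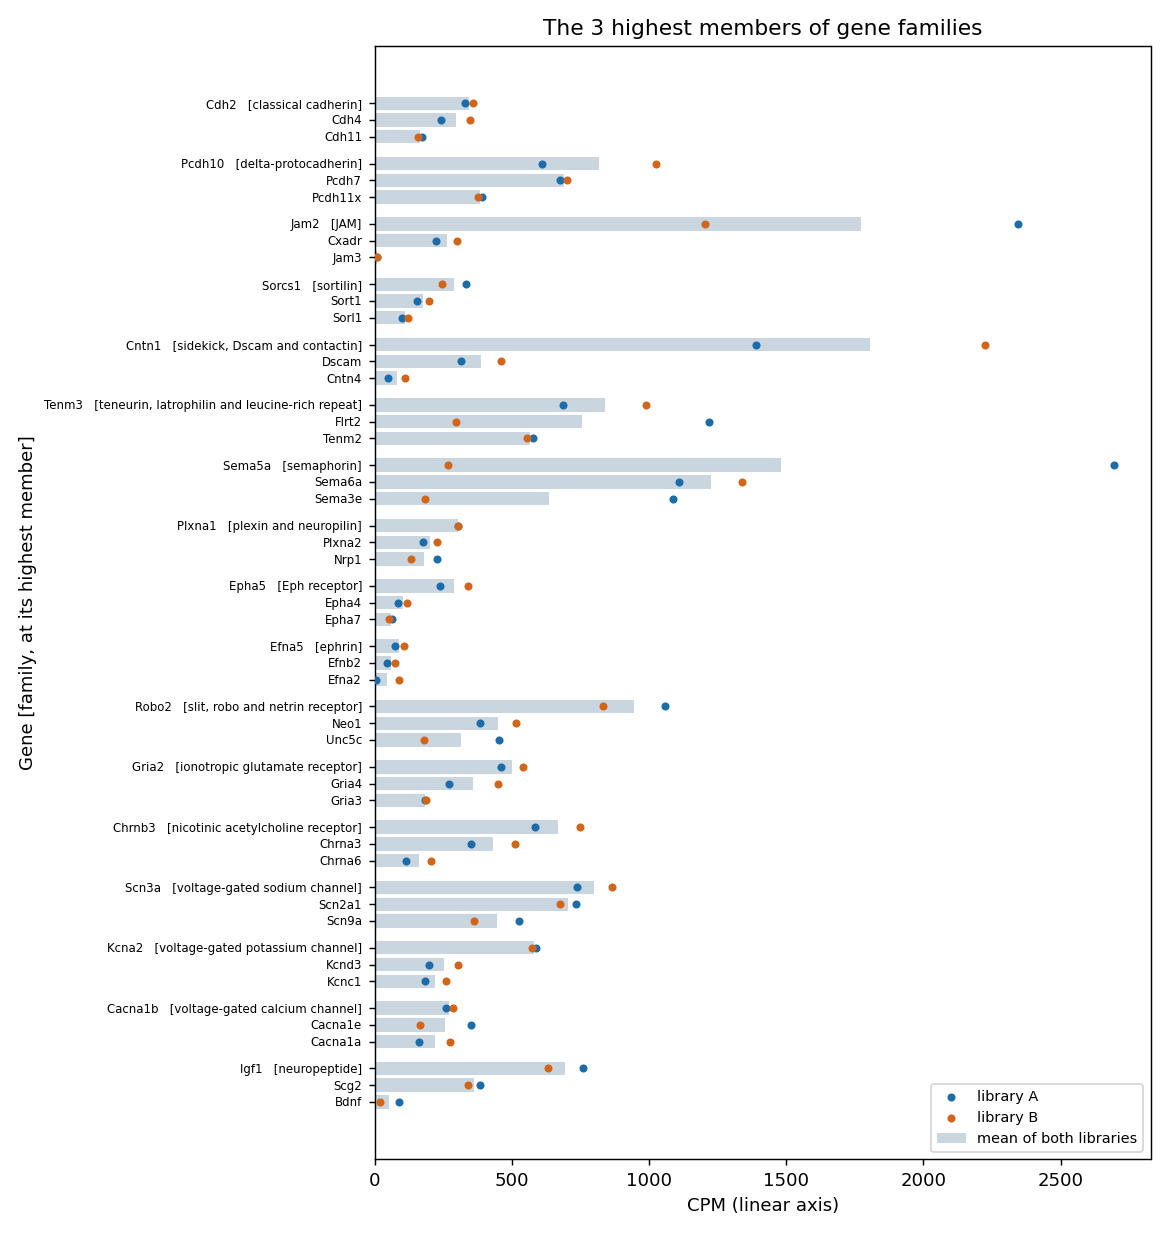
CPM, on a linear axis from 0, of the 3 highest members of gene families, without the inhibitory receptors. Bars are the mean of both libraries and points the single libraries. Jam2 and Cntn1 stand highest in their families in each library, and Sema5a is 2693 CPM in A against 265 in B.

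Of the glutamate receptor subunits Gria2 (501 ± 56.7 CPM), Gria4 (358 ± 127 CPM) and Gria3 (183 ± 2.43 CPM) led, and Gria2 exceeded Gria1 8.04-fold (95% interval 3.23 to 20.01), a log2 ratio of 3.01 that was 2.15 with length correction. Of 19 inhibitory receptor subunit genes 15 were detected, among them Gabrb2 at 275 ± 41.4 CPM. The nicotinic subunits were led by Chrnb3 (666 ± 114 CPM), Chrna3 (430 ± 112 CPM) and Chrna6 (161 ± 65.1 CPM). Sodium channel genes were led by Scn3a (800 ± 89.5 CPM), Scn2a1 (705 ± 41.5 CPM) and Scn9a (444 ± 115 CPM), and potassium channel genes by Kcna2 (580 ± 9.02 CPM), Kcnd3 (252 ± 75.4 CPM) and Kcnc1 (221 ± 55.3 CPM). Calcium channel genes were led by Cacna1b (272 ± 17.6 CPM), Cacna1e (258 ± 130 CPM) and Cacna1a (218 ± 78.7 CPM), with Cacna1b over Cacna1e at 1.05-fold (95% interval 0.412 to 2.70). Of the 27 secreted peptide and factor genes 10 were detected. Their highest members were Igf1, a growth factor, at 695 ± 91.8, the granin Scg2 at 362 ± 30.8 and the neurotrophin Bdnf at 88.9 and 18.0 CPM.

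The agreement between the 2 libraries set the limits of these values. Over the 16969 genes with a count, Pearson's r of the log2 levels was 0.917 and Spearman's rho 0.908 across genes, which are not independent replicates. Among the 7769 genes with a mean CPM of at least 10, r was 0.807 and 70.9% lay within 2-fold. The biological coefficient of variation was 0.507. By the exact binomial test 6008 of 14107 genes, or 42.6%, differed beyond counting noise with Benjamini-Hochberg adjustment. Of these, 4550 were higher in B and 1458 in A. TMM scaling moved all log2 ratios of B over A by 0.39 towards A and gave 3153 higher in B and 2092 in A. The extremes lay on the side of A. With the pseudocount of 0.5 in the ratio, 53 genes were at least 16-fold higher in A at a mean CPM of at least 10, against 3 in B. The pseudocount shrinks the ratios of genes near 0 in either library. The 10 largest in A were Syce2 (3379 and 4.44 CPM), Mcm10 (318 and 0.291 CPM), Tmem245, Grm6, Zfp418 (728 and 8.44 CPM), Papolb (246 and 2.69 CPM), H2-Ke2 (358 and 4.51 CPM), Lpar4 (190 and 2.26 CPM), Slc22a12 (96.5 and 0.946 CPM) and Fndc3c1 (36.6 and 0.0728 CPM). The 10 largest in B, of which 3 reached 16-fold with the pseudocount and more without it, were Kcnd1 (0.253 and 23.8 CPM), Mir6236 (5.05 and 171 CPM), Efna2, Hmgxb3 (1.01 and 22.3 CPM), Susd4 (1.52 and 28.2 CPM), B630019K06Rik (1.26 and 23.1 CPM), Inadl (1.14 and 21.1 CPM), Arhgef6 (1.52 and 24.8 CPM), Bbs2 (3.41 and 47.5 CPM) and Swt1 (2.40 and 34.9 CPM).

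**Figure D4:**
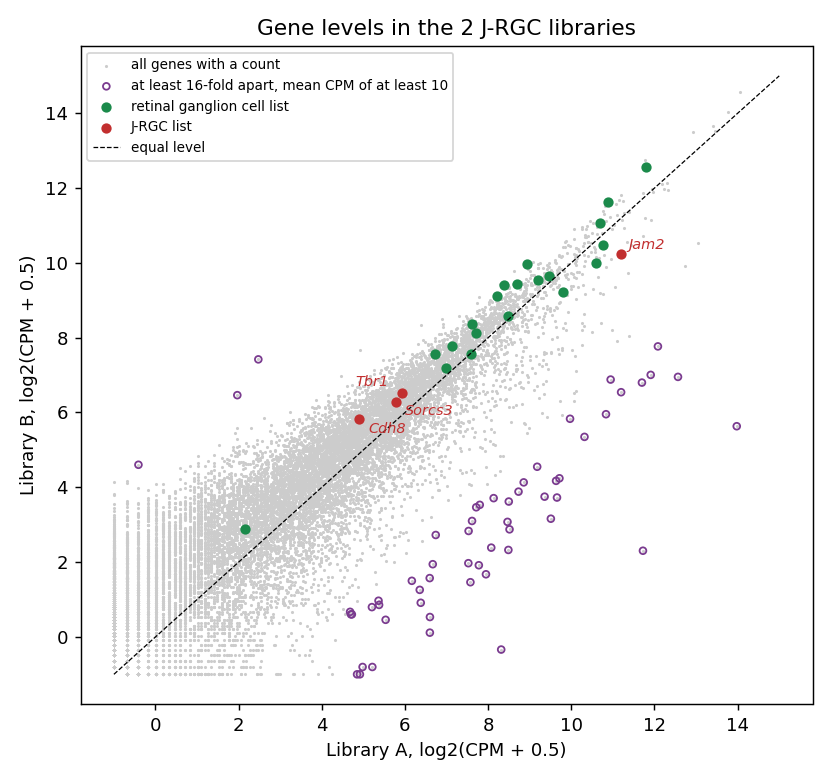
Level of each gene in library A (horizontal) and library B (vertical), as log2(CPM + 0.5). Green and red points are the ganglion cell and J-RGC lists, and the dashed line marks equal levels. Circles are the 53 genes at least 16-fold higher in A and the 3 at least 16-fold higher in B, with the pseudocount in the ratio and a mean CPM of at least 10. The ganglion cell genes lie near the line, 18 of 20 within 2-fold.

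By list, 6 of 39 stood apart between the libraries against random lists matched on level, where 7.0% of simulated lists of 12 genes with no shift did so. The median log2 ratio of B over A was 0.53 for the ganglion cell list against 0.19 for matched lists, 0.93 for classical cadherins against 0.37, 0.83 for sidekicks, Dscams and contactins against 0.31, and 0.81 for ionotropic glutamate receptors against 0.37. It was lower than in matched lists for cycling cell genes, at -0.42 against 0.56, and for secreted peptides and factors, at -0.15 against 0.57. The glutamate receptor list lay close to the limit, at the 98.2 percentile, and its call ended under 4 of 5 alternatives. It missed narrowly at the 97.44 percentile with TMM scaling, 97.41 with DESeq2 scaling and 97.48 without the 53 genes above, where its log2 ratio stayed at 0.81. With members of at least 10 counts only it was 0.74, at the 95.7 percentile. The ganglion cell call ended without Nefl, the list's highest member, at 0.42 and the 94.7 percentile. The lists of handling genes did not stand apart. Jun (69.3 ± 25.4 CPM), Egr1 (62.3 ± 2.76 CPM), Dusp1 (17.1 ± 10.5 CPM) and Fos (11.1 ± 6.47 CPM) led the immediate early and stress list, at the 63.9 percentile. Sox11, Cdkn1a (72.4 ± 13.1 CPM) and Bcl2l11 (23.4 and 26.6 CPM) were among the highest of the apoptosis list, at the 18.0 percentile. Xist, made from the inactive X chromosome of females, stood at 633 and 359 CPM, and the Y-linked genes Eif2s3y, Ddx3y and Kdm5d at 31.2 and 69.5, 29.6 and 48.5, and 21.7 and 42.1 CPM. Uty stood at 16.0 and 46.5 CPM, and genes of both sexes were thus read in each pool.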

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

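The tests of depth, scaling and starting molecules, of the further mural list and of the further microglia list were written after the main lists were seen and before the values they measure.

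Reads that the gene counts do not use made up most of each file. In library A 54.34% of reads fell outside annotated features and 18.54% aligned to several places, and in library B 47.94% and 20.76%. They were flagged because they lie outside the gene counts. What they come from was not tested, and the limit given above on reads that aligned to several places applies.

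The genes at least 16-fold higher in library A, with the pseudocount in the ratio, were 53, at a median of 246 CPM in A and 6.11 CPM in B. They took 5.58% of the gene counts of A and 0.125% of those of B. Counting error at lower depth was already allowed for when these genes were chosen, since the binomial test takes the library totals. A random part of library B as deep as A, set against the rest of B, gave 0 such genes. That outcome was thus fixed in advance and adds no evidence. Scaling by totals is argued against by the size and direction of the TMM shift, 0.39 on the log2 scale towards A. The count of 68 with TMM factors follows from that shift and is no further evidence. A candidate explanation is that library A began from fewer molecules, some of which were amplified far beyond the rest: with B thinned to the total of A, 549 genes had 0 counts in A and at least 10 in B against 84 the other way, 6.54 times as many. A different mix of cells in B could also give it more genes, so a biological difference between the litters stays open. Of the 53 genes only Grm6 is on a list of another cell type. Those lists hold few genes, so that count weighs neither way.

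The mural cell genes Rgs5, Pdgfrb and Kcnj8 were higher in library A, with a median log2 ratio of B over A of -2.05. Scaling is argued against by the TMM shift, which moves all ratios by 0.39 towards A. The value of -2.43 with TMM factors follows from that shift and is no separate test. RNA of mural cells in A cannot be told apart from uneven amplification. Of a second mural list, 13 members had at least 10 counts, with a median log2 ratio of -0.0485 and an SD of 1.72, and 7 of them were higher in A. That value met the bound set in advance against mural RNA. After it was seen that bound was set aside, because only 3 members reached a mean CPM of 10. Of these, Abcc9 (165 and 66.6 CPM) and Vtn (28.9 and 2.04 CPM) were higher in A, and Cspg4 (11.1 and 14.5 CPM) was not. Kcnj8, on which the pattern partly rests, also lay under that level, at 6.37 ± 5.10 CPM. Setting the bound aside was thus a choice made after the outcome, and the second list decides neither way. Of all genes with a mean CPM of at least 10 outside the vascular list, 5.33% were at least 3-fold higher in A.

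Microglia genes were read in both libraries, 7 of the 12 on the list above 10 CPM in each. Cells or RNA of microglia in the sort are a candidate explanation: of a second list of 18 genes, 83.3% were at a CPM of at least 1 in both libraries, including Ctsd (222 ± 69.1 CPM), Mpeg1 (136 ± 90.1 CPM), Itgam (40.5 ± 9.92 CPM), Laptm5 (21.98 and 21.97 CPM) and Cd53 (20.4 ± 4.42 CPM). Many genes pass that threshold, 11241 of the 16969 with a count, so the share alone says little. The second list's level was at the 89.1 and 90.85 percentile of random lists in A and B. Ctsd, Cst3 and Sparc are also made by other retinal cells, and Trem2, Spi1 and Selplg lay at or below 3.20 CPM in both libraries. The gate on the fluorescent protein would remove microglia that do not carry it, and whether whole cells, cells attached to neurons or free RNA gave these reads was not tested.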

How the results depend on the processing

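Of the alternatives, thinning of library B in the count of genes beyond noise, lists without genes at 0, the ratio of lists without the 53 genes, and all alternatives for ratios of genes that are not neighbours in rank were added after seeing the data. Detected genes stayed within 1.5 times of 11241 under every setting tried, from 8283 at a CPM of 5 to 13130 in B alone, and 11243 with B thinned. All other cell type lists that could be compared stayed below the ganglion cell list. These were 12 under each setting except length correction, where 11 were compared because only 71.4% of erythrocyte genes had a length. The J-RGC list stayed above 3 of 4 type lists throughout, under the limit given above on how its genes were chosen. The coefficient of variation moved from 0.507 to 0.683 with no filter beyond 1 count, 0.400 at a CPM of at least 10 in both and 0.489 by DESeq2, where the cause was not tested. Without a fold minimum 10974 genes differed beyond counting noise. The share of counts was 10.4% for the 10 and 27.9% for the 100 highest genes. Families with a separated leading member numbered 2 or 3, but they were not the same families in each setting. Of the 3 named above only Cntn1 over Dscam kept its call throughout. Lists apart numbered 5 under each alternative. The order of close genes was not stable, on the log2 scale of the ratio. Ebf3 over Pou4f2 ranged from -0.33 to 0.54 when 1 library was left out and was -0.71 with length correction. Leaving out 1 library gave -0.15 to 0.55 for Pcdh10 over Pcdh7, -0.82 to 1.74 for Tenm3 over Flrt2, -2.34 to 1.28 for Sema5a over Sema6a, -0.43 to 0.78 for Cacna1b over Cacna1e, -0.15 to 0.85 for Tbr1 over Nefh and -0.65 to 0.40 for Tbr1 over Tbx20. Length correction gave -0.39 for Pcdh10 over Pcdh7, -0.15 for Tenm3 over Flrt2, -0.33 for Sema5a over Sema6a, -0.25 for Gria2 over Gria4, -1.04 for Igf1 over Scg2, -0.15 for Tbr1 over Cartpt and 1.11 for Tbr1 over Tbx20. The intervals of these ratios held 0 except for Sema5a over Sema6a in B alone, and the cause was not tested beyond the library left out or the length correction itself. Of the other values 1051 kept their call or moved by less than their spread, 66 moved by more, and 15 kept their direction but lost their call. Depth limits little above 10 CPM, and the spread between libraries is the larger error. At a mean CPM from 1 to 10 the SD of the log2 ratio was 1.49, and 291 of 5054 such genes had no count in A against 30 in B.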

Other observations

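The lists of this part were written after the main lists were seen and before their members were looked at. Genes of the release machinery were high: all 26 synaptic vesicle and release genes were detected, 14 of them above 100 CPM in both libraries, with Syt1 at 1617 ± 549, Pclo at 1685 ± 489, Syn1 at 852 ± 60.1 and Syn3 at 697 ± 135 CPM, whereas the fast calcium sensor Syt2 stood at 7.96 ± 4.46 CPM. Of 18 axon transport and neurofilament genes 16 were above 100 CPM in both libraries, among them the kinesin genes Kif1a (1776 ± 308 CPM), Kif5a (1090 ± 201 CPM) and Kif5c (994 ± 224 CPM), and Prph had no counts. Of 13 transmitter genes 5 were detected. Slc17a7 stood at 10.99 and 0.509 CPM, and Slc17a6 exceeded it 158-fold in A (95% interval 32.4 to 766) and 2825-fold in B (499 to 15994). Slc18a2, the vesicular monoamine transporter, stood at 323 ± 69.4 CPM, while Th (0.0995 ± 0.0379 CPM) and Tph2 (0.645 ± 0.734 CPM), which make dopamine and serotonin precursors, lay near the floor.

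Of 18 trophic receptor genes 13 were detected. Ntrk2 (TrkB) stood at 197 ± 88.6 CPM, Ret at 155 ± 70.1, Igf1r at 132 ± 3.59 and Ntrk3 at 112 ± 6.96 CPM. All 7 metabotropic glutamate receptor genes were detected, with Grm7 at 59.1 ± 8.53 CPM. Of 17 dopamine, serotonin and muscarinic receptor genes 6 were detected, with Htr1d at 19.4 ± 11.5 and Drd2 at 11.9 ± 0.374 CPM. Of the oligodendrocyte lineage list Olig1, Olig2 and Sox10 had no counts, and Mbp stood at 8.48 ± 3.95 CPM. Of the ribosomal RNA list 5 of 6 symbols were in the data, with Rn45s at 17091 and 24519 CPM and Gm20594 at 2650 ± 47.3 CPM.

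The 4 Y-linked genes had a median log2 ratio of B over A of 1.04, against 0.37 in random lists matched on level, at the 94.4 percentile, so the list did not stand apart. Each of them was higher in B, while Xist was higher in A (633 and 359 CPM), so a different share of males stays open. Of 5 further Y-linked genes 1 had at least 10 counts, too few to test a different share of males. Both tests of that difference were run, neither decided, and they were then set aside to keep to 3 weighed patterns.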
